A study of Homo sapiens with 9 samples.

How the data were processed

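The data are expression profiles of IMR-90 cells, an established line of human fetal lung fibroblasts, measured on the Affymetrix Human Gene 1.0 ST array. Per the labels, cells were transfected with Lipofectamine and locked nucleic acid (LNA) oligonucleotides, and total RNA was extracted with Trizol 48 hours later. An LNA oligonucleotide complementary to a microRNA binds it and keeps it from its target mRNAs. The 9 arrays fall into 3 groups of 3, which per the labels received a scrambled oligonucleotide at 100 nM, the miR-29 knockdown oligonucleotide at 50 nM, or the same oligonucleotide at 100 nM. The labels do not say whether the total oligonucleotide amount at 50 nM was made up to 100 nM. They also do not say whether the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

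The authors deposited 1 value per probe set and array on a log2 scale. Per the submitters' processing notes these values came from the RMA procedure in Affymetrix Expression Console, which corrects background, applies quantile normalization across arrays and summarises the probes of a set; program versions and log base are not given in the sources used here. The base was taken from the deposited values, which run from 0.814 to 13.3: on a natural or decimal log scale the highest would exceed the range of a 16-bit scanner, whose log2 maximum is 16. Quantile normalization sets the arrays to nearly the same distribution, so a change shared by most genes would not appear, and summarising probes compresses differences of dim and of very bright probe sets. The array gives no read depth, and its number of arrays limits the precision.

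The table holds 33297 probe sets. The platform annotation gave exactly 1 gene symbol to 19460 of them, several to 1754 and none to 12083. Of those with 1 symbol, 19429 matched a current gene table made on the assembly GRCh38.p14 and 31 did not; 0 symbols needed updating. The files name no genome build, so no coordinates are given. Genes were tested if a probe set with 1 symbol had a mean log2 value of at least 6 over the 9 arrays, and the brightest such probe set stood for a gene with several. This left 10294 genes of 18417, and 386 of these had more than 1 probe set above the minimum. Among genes called, 2 of 37 with several probe sets at 50 nM and 3 of 52 at 100 nM had a further probe set with the opposite sign.

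Each gene was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with its default prior). The model had 1 coefficient per group over all 9 arrays, so that the 3 groups shared an estimate of the spread, with 9.81 total degrees of freedom per gene. The 3 comparisons were 50 nM against scrambled, 100 nM against scrambled and 100 nM against 50 nM. All gene p-values are two-sided and were adjusted by the Benjamini-Hochberg method over the genes tested in a comparison, with a threshold of 0.05. Errors of fold changes are standard errors from this fit, and errors of group means are standard deviations. Figures were drawn with Python 3.11.15.

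Before the data were examined, 23 gene lists were fixed from general knowledge: reported miR-29 targets, fibrillar collagens, basement membrane genes, elastic fibre and matrix glycoprotein genes, collagen processing enzymes, matrix proteases and inhibitors, integrins, DNA methylation and demethylation enzymes, myofibroblast contractile genes, TGF-beta response genes, growth factor and IGF signalling genes, cell cycle genes, p53 target genes, interferon response genes, inflammatory cytokine genes, endoplasmic reticulum stress genes, cholesterol synthesis genes, heat shock and immediate early genes, microRNA pathway genes, ribosomal protein genes, and markers of epithelial, endothelial and leukocyte cells. The lists overlap: 6 of the fibrillar collagens tested, 4 basement membrane genes and 4 growth factor genes are also reported targets. So are 3 elastic fibre and matrix glycoprotein genes, 3 DNA methylation and demethylation enzymes, 2 collagen processing enzymes and 2 matrix proteases and inhibitors. The integrin, TGF-beta, p53, cholesterol and microRNA pathway lists each hold 1. Calls of these lists are therefore not independent of that of the reported targets. Some reported targets may have been named as such from experiments like this, so that list is not independent of the design. Each list was set against all other genes tested with limma's camera at its preset correlation of 0.01 between genes, two-sided, and the 69 list tests were adjusted together. Camera with a correlation estimated from the arrays stood beside it. Limma's fry was also run; it tests whether a list's genes move, on balance, one way, and does not compare them with other genes, so its values are a different test and appear only in the account of the settings. With the estimated correlation 0 of the 69 list tests passed, so each list's call with these settings rests on the preset correlation. In every list called with the deposited scaling, the median kept its sign when arrays were centred on their medians or quantile normalization was applied again.

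The genes named in the text follow a rule fixed at the same time. In each comparison against scrambled these are the 10 largest rises and 10 largest falls among genes past the threshold whose 3 knockdown arrays all lay beyond all 3 scrambled arrays. To these come 14 genes named whether changed or not, and in each list at most 4 members with the largest absolute change. Between the doses the largest difference each way is named, since none passed. Genes named outside this rule are said to be so. Calls and overlaps were recomputed with other filters, variance priors, scalings, array weights and fits, with a replicate block, and without each array in turn. List tests were recomputed with other filters, scalings and methods of list test, with the replicate block and without each array in turn. They were not recomputed with other variance priors, array weights or fits of only the 2 groups compared. A test of miR-29 seed sites in 3′ untranslated regions, also fixed at that time, was not run because no sequences were used here.

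The procedure was tested on simulated data with each gene's spread on these arrays, in which 200 of 10294 genes were changed. Noise was drawn independently for each gene, so the spread shared between genes on these arrays was left out. The rates below may therefore not carry over to these data. At 50 nM against scrambled it called 71% of the genes changed 1.25-fold and 99% of those changed 1.5-fold, with 4.49% of calls false. At 100 nM against scrambled it called 77% and 100% of these, with 3.28% false, and between the doses 75% and 98%, with 5.98% false. Because both knockdown groups share the scrambled arrays, their shared calls and the correlation and covariance of their fold changes were also computed in 100 simulations of unchanged groups.

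A main axis of spread within groups was taken as the first singular vector of the deviations of all genes tested from their group means. Each array's score is its mean deviation from the mean of all arrays over the 100 genes loading highest, minus that over the 100 loading lowest. Because the score comes from these same arrays, fitting it as a covariate lowers the spread within groups and favours more calls. In weighing explanations, an effect had to exceed the stated bound by more than 1 standard error before it was held to exclude an explanation; this margin was added after the values were seen.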

Results

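To find mRNAs that respond to miR-29, a family of microRNAs known to repress collagens and other matrix genes, mRNA was profiled in IMR-90 fibroblasts 48 hours after transfection. The 3 groups were a scrambled LNA oligonucleotide at 100 nM, the miR-29 knockdown LNA at 50 nM and the same LNA at 100 nM, with 3 arrays in each. Each array's median over all 33297 probe sets lay between 5.763 and 5.782 on the log2 scale on scrambled arrays and between 5.785 and 5.832 on knockdown arrays. Every knockdown array's median was thus above every scrambled array's. The main axis of spread within groups held 55.1% of that spread. Its score was 0.80 on 50 nM replicate 2 and 0.39 on 100 nM replicate 3, against -0.40 to 0.10 on the other 7 arrays. Its group means were -0.22 ± 0.21 (SD, n = 3) in scrambled, 0.11 ± 0.60 at 50 nM and 0.11 ± 0.27 at 100 nM. The higher mean at 50 nM came from replicate 2: the other arrays of that group scored -0.18 and -0.29, within the scrambled range of -0.40 to 0.01. At 100 nM the scores were -0.15, 0.10 and 0.39. Of 77 small nuclear and nucleolar RNAs tested, 9 were among the 100 genes loading lowest on the axis and 2 among the 100 loading highest, a count made after the data were seen. Their median loading was -0.036, against -0.039 for protein-coding genes. Of the 77, 1 rose and 8 fell at 50 nM, and 0 rose and 11 fell at 100 nM. Of 9868 protein-coding genes 484 rose and 610 fell at 50 nM, and 479 rose and 1008 fell at 100 nM.

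The targeted microRNA itself is read on this array only through probe sets for its precursors, both below the brightness minimum and therefore not tested. The MIR29A probe set had log2 values of 4.95 ± 0.10 (SD, n = 3) in scrambled, 5.03 ± 0.36 at 50 nM and 4.79 ± 0.34 at 100 nM. The MIR29B1 probe set had 2.29 ± 0.24, 2.03 ± 0.16 and 1.92 ± 0.12 in the same order. An LNA that binds the mature microRNA need not change its precursor, so these values do not check the knockdown.

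At 50 nM the genes with the largest rises against scrambled, among those whose arrays did not overlap, included secreted and membrane proteins, metabolic enzymes and an extracellular matrix linker. GPNMB, a transmembrane glycoprotein of lysosomes and melanosomes, rose 3.39-fold (log2 1.76 ± 0.14, SE, n = 3 per group, adjusted p = 0.000105). PDK4, a kinase that inhibits pyruvate dehydrogenase, rose 2.44-fold (1.29 ± 0.07, adjusted p = 2.7e-05) and FBXO32, a ubiquitin ligase subunit known from muscle atrophy, 2.43-fold (1.28 ± 0.10, adjusted p = 8.22e-05). NID1, which links laminin and collagen IV networks in basement membranes, rose 2.06-fold (1.04 ± 0.07, adjusted p = 5.89e-05). BMP2, a secreted growth factor, rose 2.11-fold, the membrane peptidase MME 2.08-fold and the prostaglandin synthase PTGS2 2.07-fold. The glucosyltransferase POGLUT2 rose 2.01-fold, the aldo-keto reductase AKR1C1 1.91-fold and the transcriptional repressor PRDM1 1.87-fold. Among genes whose arrays did not overlap, the largest falls were those of RNU5D-1, a small nuclear RNA of the spliceosome, which fell 2.9-fold (log2 -1.54 ± 0.19, adjusted p = 0.00102), and SERPINB7, a serine protease inhibitor, which fell 2-fold (log2 SE 0.11, adjusted p = 0.000595). HAS2, which makes hyaluronan, fell 1.85-fold, the transporter gene SLC16A4 1.81-fold, the steroid dehydrogenase gene HSD17B6 1.76-fold and TPD52L1 1.74-fold. The receptor-like gene PDGFRL fell 1.73-fold, the checkpoint kinase gene CHEK1 1.63-fold, TMEM52B 1.61-fold and the adhesion molecule gene VCAM1 1.59-fold. In each of these genes all 3 arrays at 50 nM lay beyond all 3 scrambled arrays. Within each dose group RNU5D-1 was lowest on the array scoring highest on the axis (6.54 on 50 nM replicate 2 and 6.28 on 100 nM replicate 3), and with the axis covariate its log2 change was -1.32 at 50 nM and -1.62 at 100 nM.

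**Figure D1:**
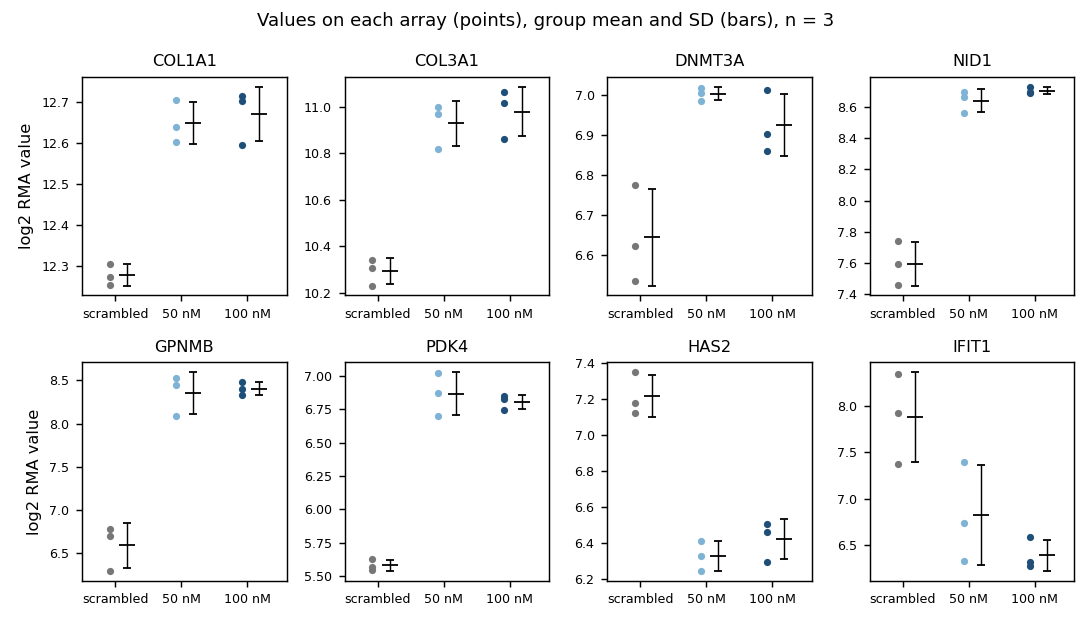
Log2 RMA values (vertical axis) of 8 genes on each of the 9 arrays, as points, with the group mean and SD (n = 3) as a bar beside them; vertical axes differ between panels and do not start at 0. COL1A1, COL3A1, DNMT3A, NID1, GPNMB and PDK4 lie higher on all knockdown arrays than on all scrambled arrays, HAS2 lies lower, and the IFIT1 arrays overlap between scrambled and 50 nM.

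Reported miR-29 targets rose as a group at 50 nM. Of 39 tested, 25 rose (29 adjusted over the list alone), 0 fell and 14 did not pass, with a median log2 change of 0.30 (camera adjusted p = 1.75e-20; adjusted p = 0.0885 with an estimated correlation). COL3A1, a fibrillar collagen of the fibroblast matrix, rose 1.55-fold (0.64 ± 0.07, adjusted p = 0.000393), INSIG1, a regulator of sterol synthesis, by 0.63 on the log2 scale, COL4A1 of the basement membrane 1.53-fold (0.61 ± 0.06, adjusted p = 0.00034) and the transcriptional repressor HBP1 by 0.61. Of the genes named in advance, COL1A1 rose 1.29-fold, FBN1 1.24-fold, LAMC1 1.27-fold, ITGA11 1.39-fold and ADAMTS9 1.42-fold. DNMT3A, a DNA methyltransferase, rose 1.28-fold (0.36 ± 0.06, adjusted p = 0.00691), and MCL1, which protects from apoptosis, 1.27-fold (0.34 ± 0.08, adjusted p = 0.0238). TET3, an enzyme of DNA demethylation, rose 1.23-fold (0.30 ± 0.07, adjusted p = 0.0282). COL5A3 (0.13 ± 0.09, adjusted p = 0.359) and ELN (0.01 ± 0.08, adjusted p = 0.961) did not pass, and DNMT3B and TET1 were too dim to be tested. The call of MCL1 was lost without scrambled replicate 1, scrambled replicate 3, 50 nM replicate 1 or 50 nM replicate 3 (adjusted p from 0.0652 to 0.0753), and that of TET3 without any scrambled replicate or 100 nM replicate 2 (adjusted p from 0.0513 to 0.102). Without these single arrays the log2 change was 0.27 to 0.35 for MCL1 and 0.28 to 0.34 for TET3. Both calls were also lost in a fit of only the 2 groups (adjusted p = 0.0613 for MCL1 and 0.086 for TET3) and without the brightness minimum (0.0527 and 0.0618). There the log2 changes stayed at 0.34 and 0.30.

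The fibrillar collagen, basement membrane and integrin lists moved up at 50 nM. Of 9 fibrillar collagens 5 rose (6 adjusted over the list alone) and 0 fell, led by COL3A1 and COL5A2 (log2 0.59). The list's median was 0.20 (adjusted p = 1.88e-06; adjusted p = 0.0885 with an estimated correlation). Of 17 basement membrane genes 9 rose and 0 fell (10 and 1 adjusted over the list alone), among them the laminin chain gene LAMA1 (0.82) and COL4A5 (0.57; camera adjusted p = 1.25e-06; adjusted p = 0.0982 with an estimated correlation). Of 11 integrins, the cell's matrix receptors, 6 rose and 0 fell (7 and 1 adjusted over the list alone), with ITGA8 up by 0.85 and ITGA2 by 0.56 (adjusted p = 0.00011; adjusted p = 0.424 with an estimated correlation). Of 21 matrix proteases and inhibitors 6 rose and 1 fell (6 and 1 adjusted over the list alone), led by the membrane collagenase MMP14 (0.62), ADAMTS9 (0.51) and ADAM19 (0.48; adjusted p = 0.0393; adjusted p = 0.484 with an estimated correlation). That call was lost without scrambled replicate 1 (0.0752), without 50 nM replicate 3 (0.0903), without the brightness minimum (0.122) and without the 3 arrays highest on the axis in their group (0.0507). Of 27 elastic fibre and matrix glycoprotein genes 5 rose (6 adjusted over the list alone) and 0 fell (2), including the proteoglycan LUM (0.68) and SPARC (0.41), and the list did not pass (adjusted p = 0.0975). It passed with the axis covariate (0.0431) and with quantile normalization applied again (0.0347), but not there with an estimated correlation (adjusted p = 0.426 and 0.189). Of 19 collagen processing enzymes 5 rose and 2 fell (7 and 2 adjusted over the list alone). The procollagen peptidase ADAMTS2 rose by 0.71 and the collagen chaperone SERPINH1, a reported target, by 0.52. The lysyl oxidase relative LOXL3 fell by 0.39. The list did not pass (adjusted p = 0.0886): its median was -0.001 and its mean 0.08. It passed upward with quantile normalization applied again (0.0267, where the median was 0.01) and with a brightness minimum of 7 (0.0335), but not there with an estimated correlation (adjusted p = 0.344 and 0.468).

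Contractile genes of myofibroblasts fell at 50 nM: 5 of 12 fell (6 adjusted over the list alone), 0 rose and 7 did not pass (adjusted p = 0.000253; adjusted p = 0.349 with an estimated correlation). CNN1, an actin-binding protein of smooth muscle, fell by 0.55 on the log2 scale, LMOD1 by 0.46, ACTG2 by 0.41 and ACTA2, the smooth muscle actin used as a myofibroblast marker, by 0.31.

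Of 23 TGF-beta response genes 6 rose and 1 fell (7 and 3 adjusted over the list alone), among them the repressor TGIF1 (0.39), JUNB (0.33) and ID1 (0.29; adjusted p = 0.00157; adjusted p = 0.349 with an estimated correlation). Of 21 growth factor and IGF signalling genes 5 rose and 1 fell (6 and 1 adjusted over the list alone), with PDGFD up by 0.47 and PDGFRB by 0.29 (adjusted p = 0.0193; adjusted p = 0.424 with an estimated correlation). INSIG1, also in this list though it regulates sterol synthesis and is a reported target, was among those that rose. The growth factor list's call was lost without scrambled replicate 1 (0.0752), with a brightness minimum of 7 (0.0512) and without the 3 arrays highest on the axis (0.0649). Of 18 p53 target genes 3 rose and 0 fell (7 and 0 adjusted over the list alone), namely GDF15 (0.48), PPM1D (0.26) and TNFRSF10B (0.20; adjusted p = 0.00588; adjusted p = 0.349 with an estimated correlation); TNFRSF10B was chosen after its value was seen, and PPM1D is itself a reported target. Of 17 cholesterol synthesis genes 3 rose and 0 fell (4 and 0 adjusted over the list alone): INSIG1, which is a reported target and restrains sterol synthesis, HMGCS1 (0.38) and DHCR7 (0.22; adjusted p = 0.0249; adjusted p = 0.571 with an estimated correlation). That call was lost without 50 nM replicate 3 (0.143).

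The remaining lists did not pass at 50 nM. Of 17 endoplasmic reticulum stress genes 4 rose (4 adjusted over the list alone) and 0 fell, namely ASNS (0.56), CHAC1 (0.41), HERPUD1 (0.32) and ATF4 (0.25; list adjusted p = 0.0759). The list passed without 50 nM replicate 2 (0.0369), with the axis covariate (0.0431) and with quantile normalization applied again (0.0456). Of 13 cell cycle genes 3 fell (3 adjusted over the list alone) and 0 rose, namely AURKA by 0.64, CCNB1 by 0.37 and MCM6 by 0.21 (list adjusted p = 0.401); with members below the brightness minimum included the list passed downward (adjusted p = 5.22e-07; adjusted p = 0.0256 with an estimated correlation). Of 8 DNA methylation and demethylation enzymes 3 rose and 1 fell (3 and 2 adjusted over the list alone, list adjusted p = 0.243), with UHRF1 falling by 0.35 and TET2 rising by 0.31. In this list DNMT3A, TET2 and TET3 are reported targets. Of 8 inflammatory cytokine genes PTGS2 rose and VCAM1 fell (3 and 3 adjusted over the list alone; list adjusted p = 0.937), and of 6 interferon response genes IFIT1 fell, by 1.06 ± 0.28 (1 adjusted over the list alone; list adjusted p = 0.332). With dim members included the interferon list passed downward (adjusted p = 8.97e-05), but not with an estimated correlation (adjusted p = 0.329). Among 10 heat shock and immediate early genes HSPH1 and EGR1 rose, 2 in all (3 adjusted over the list alone; list adjusted p = 0.28), and among 12 microRNA pathway genes AGO2 did (1 adjusted over the list alone; list adjusted p = 0.168, and 0.0456 with the axis covariate). None of 22 ribosomal protein genes passed, over all genes or over the list (list adjusted p = 0.243). Among markers of other cell types, KRT18 rose of 4 epithelial markers (list adjusted p = 0.598), TEK of 3 endothelial markers (0.41; list adjusted p = 0.0613) and 0 of 3 leukocyte markers passed (list adjusted p = 0.753). Adjusted over the list alone these counts were 1, 1 and 0. The endothelial list passed without scrambled replicate 1 (0.0482) and without 50 nM replicate 3 (0.0412). With an estimated correlation in the same settings, the stress, microRNA pathway and endothelial lists did not pass (adjusted p = 0.147 to 0.504).

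In all, 490 of 10294 genes rose and 626 fell at 50 nM (limma, adjusted p under 0.05), with a median rise of 1.24-fold and a median fall of 1.21-fold; 54 rose and 19 fell by at least 1.5-fold. In 28.6% of genes the 3 arrays at 50 nM and the 3 scrambled arrays did not overlap, where chance gives 10%. The count that fell rested partly on single arrays: it was 295 without scrambled replicate 2, 259 without scrambled replicate 3 and 377 without 50 nM replicate 1. It was also 376 in a fit of only the 2 groups and 393 without the brightness minimum, while with array weights 1028 rose and 1568 fell. With each array's axis score as a covariate, an alternative added after the data were seen, 784 genes rose and 781 fell. Rises made up 43.9% of the calls at 50 nM, 46.9% with arrays centred on their medians and 49.2% with quantile normalization applied again.

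**Figure D2:**
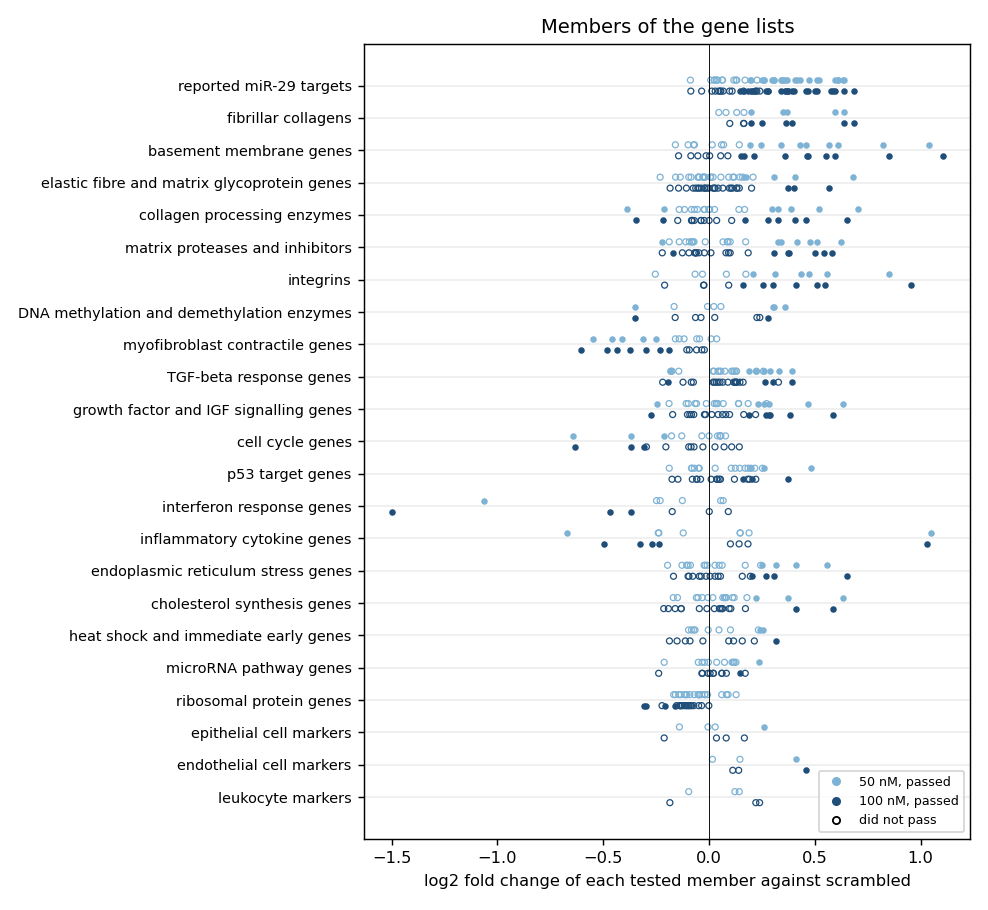
Log2 fold change against scrambled (horizontal axis) of every tested member of the 23 gene lists, at 50 nM in light and 100 nM in dark points; filled points passed the test and open points did not. All passing members of the reported targets, fibrillar collagens, basement membrane genes and integrins lie to the right of 0, and all passing contractile genes to the left.

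At 100 nM, the dose that matches the scrambled control, the largest rises among genes whose arrays did not overlap were again those of GPNMB (3.51-fold, log2 1.81 ± 0.14, SE, n = 3 per group, adjusted p = 0.000111), FBXO32 (2.38-fold, log2 SE 0.10, adjusted p = 0.000111) and PDK4 (2.34-fold, 1.23 ± 0.07, adjusted p = 3.48e-05). NID1 rose 2.15-fold, MME 2.05-fold, PTGS2 2.04-fold, BMP2 2.03-fold and POGLUT2 2.02-fold. The integrin gene ITGA8 rose 1.94-fold (0.96 ± 0.07, adjusted p = 0.000111) and the E2F family repressor E2F7 1.86-fold (0.89 ± 0.06, adjusted p = 5.93e-05). RNU5D-1 fell 3.58-fold (-1.84 ± 0.19, adjusted p = 0.000472), and IFIT1, an interferon-induced antiviral protein, fell 2.82-fold (-1.50 ± 0.28, adjusted p = 0.00706) from 7.88 ± 0.48 (SD) in scrambled to 6.39 ± 0.17. SERPINB7 fell 2.04-fold, HAS2 1.74-fold, TMEM52B 1.68-fold, SLC16A4 1.68-fold, the sarcomere protein gene MYPN 1.65-fold, HSD17B6 1.64-fold, TPD52L1 1.63-fold and PDGFRL 1.62-fold.

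Of the 39 reported targets 25 rose at 100 nM (29 adjusted over the list alone) and 0 fell, with a median of 0.24 (adjusted p = 1.38e-20; adjusted p = 0.0885 with an estimated correlation). COL3A1 rose 1.61-fold (0.69 ± 0.07, adjusted p = 0.000355), COL4A1 1.51-fold, COL1A1 1.31-fold, FBN1 1.30-fold, LAMC1 1.28-fold, ITGA11 1.42-fold and ADAMTS9 1.41-fold. DNMT3A rose 1.21-fold (adjusted p = 0.0186) and MCL1 1.27-fold (adjusted p = 0.0206). TET3 (0.24 ± 0.07, adjusted p = 0.0568), COL5A3 (0.16 ± 0.09, adjusted p = 0.224) and ELN (0.03 ± 0.08, adjusted p = 0.822) did not pass. TET3 did pass without 50 nM replicate 2 (0.0266) or 50 nM replicate 3 (0.0111), in a fit of only the 2 groups (0.0109), with array weights (0.0165), with arrays centred on their medians (0.0261) and with the axis covariate (0.0121). The DNMT3A call was lost without scrambled replicate 3 (log2 0.27, adjusted p = 0.0718), without 100 nM replicate 3 (0.24, adjusted p = 0.0735) and without the 3 arrays highest on the axis, where the change itself was smaller (0.18, adjusted p = 0.0711). The MCL1 call was lost without scrambled replicate 1, scrambled replicate 3, 100 nM replicate 1 or 100 nM replicate 2 (log2 0.29 to 0.35, adjusted p = 0.0607 to 0.079).

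Among matrix lists at 100 nM, 6 of 9 fibrillar collagens rose (7 adjusted over the list alone; adjusted p = 5.32e-08; adjusted p = 0.0885 with an estimated correlation), led by COL3A1 and COL5A2 (0.64). Of 17 basement membrane genes 10 rose and 0 fell (10 and 1 adjusted over the list alone; adjusted p = 2.16e-07; adjusted p = 0.0885 with an estimated correlation), led by NID1 and LAMA1 (0.85). Of 11 integrins 7 rose and 0 fell (7 and 1 adjusted over the list alone), with ITGA8 leading (adjusted p = 1.99e-05; adjusted p = 0.381 with an estimated correlation). Of 21 matrix proteases and inhibitors 6 rose and 1 fell (6 and 2 adjusted over the list alone), led by MMP14 (0.58) and ADAM19 (0.54; adjusted p = 0.0123; adjusted p = 0.432 with an estimated correlation); the call was lost without the brightness minimum (0.0527). Of 27 elastic fibre and matrix glycoprotein genes 3 rose, LUM (0.57), SPARC (0.40) and FBN1 (0.38), and 0 fell (3 and 0 adjusted over the list alone; adjusted p = 0.0396; adjusted p = 0.542 with an estimated correlation). That call was lost without scrambled replicate 1 (0.0851), without 100 nM replicate 1 (0.0812), without the brightness minimum (0.273) and without the 3 arrays highest on the axis (0.0592). SPARC and FBN1 are also reported targets. Of 19 collagen processing enzymes 6 rose and 2 fell (6 and 3 adjusted over the list alone), the list not passing (adjusted p = 0.0759). ADAMTS2 rose by 0.65 and LOXL3 fell by 0.35. The list's median was -0.02 and its mean 0.07. With quantile normalization applied again the median was positive, 0.015, and the list passed upward (adjusted p = 0.0115). It also passed without 100 nM replicate 2 (0.0385) and with a brightness minimum of 7 (0.0216). In none of these 3 settings did it pass with an estimated correlation (adjusted p = 0.31 to 0.466).

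Of 12 contractile genes 7 fell at 100 nM (7 adjusted over the list alone) and 0 rose (adjusted p = 0.00011; adjusted p = 0.349 with an estimated correlation), CNN1 by 0.61, ACTG2 by 0.48, LMOD1 by 0.43 and ACTA2 by 0.38. Of 22 ribosomal protein genes 4 fell (9 adjusted over the list alone) and 0 rose (adjusted p = 0.00224; adjusted p = 0.424 with an estimated correlation), among them RPS13 by 0.31 and RPL32 by 0.30. Of 23 TGF-beta response genes 3 rose and 1 fell (4 and 1 adjusted over the list alone), TGIF1 by 0.39 the most (adjusted p = 0.00518; adjusted p = 0.396 with an estimated correlation). Of 21 growth factor and IGF signalling genes 6 rose and 1 fell (6 and 1 adjusted over the list alone), with INSIG1 up by 0.59 and PDGFD by 0.38 (adjusted p = 0.0172; adjusted p = 0.424 with an estimated correlation), a call lost without scrambled replicate 1 (0.0701) or the 3 arrays highest on the axis (0.0739). INSIG1 is in this list but regulates sterol synthesis and is a reported target. Of 18 p53 target genes 3 rose and 0 fell (3 and 0 adjusted over the list alone), led by GDF15 (0.37; adjusted p = 0.0396; adjusted p = 0.424 with an estimated correlation). This call was lost without scrambled replicate 1 (0.0752), 100 nM replicate 1 (0.0812), the 3 arrays highest on the axis (0.0834) or the brightness minimum (0.143). Of 17 endoplasmic reticulum stress genes 4 rose and 0 fell (4 and 0 adjusted over the list alone), with ASNS, which makes asparagine, up by 0.65 and CHAC1, which degrades glutathione, by 0.31 (adjusted p = 0.0353; adjusted p = 0.424 with an estimated correlation). The chaperone HSPA5, named after its value was seen, did not pass (-0.04, adjusted p = 0.673). The list's call was lost without 50 nM replicate 2 (0.0538), 100 nM replicate 1 (0.0812), the 3 arrays highest on the axis (0.0592) or the brightness minimum (0.0987). Of 3 endothelial markers tested TEK rose, by 0.46 (1 over all genes and 2 adjusted over the list alone; list adjusted p = 0.0129; adjusted p = 0.244 with an estimated correlation).

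The other lists did not pass at 100 nM. Of 17 cholesterol synthesis genes 2 rose, INSIG1 and HMGCS1 (2 adjusted over the list alone; list adjusted p = 0.144); the list passed with a brightness minimum of 7 (0.0151), with quantile normalization applied again (0.0369) and with the axis covariate (0.0362). Of 13 cell cycle genes 3 fell (5 adjusted over the list alone), AURKA by 0.63 the most (list adjusted p = 0.243, and 5.22e-07 with dim members included, where adjusted p = 0.0256 with an estimated correlation). Of 6 interferon response genes 3 fell (3 adjusted over the list alone): IFIT1, IFI6 by 0.47 and RIGI by 0.37 (list adjusted p = 0.156; 1.16e-05 with dim members included and 0.036 with a brightness minimum of 7). With an estimated correlation in the same settings, the cholesterol and interferon lists did not pass (adjusted p = 0.247 to 0.525). Of 8 inflammatory cytokine genes PTGS2 rose and 4 fell, VCAM1 by 0.50 and CCL2 by 0.33 among them (2 and 4 adjusted over the list alone; list adjusted p = 0.987, median -0.07 and mean 0.02). DNMT3A rose and UHRF1 fell of 8 DNA methylation and demethylation enzymes (3 and 2 adjusted over the list alone; list adjusted p = 0.493, median -0.005 and mean 0.02). EGR1 rose of 10 heat shock and immediate early genes (2 and 2 adjusted over the list alone; list adjusted p = 0.378), and DICER1, a reported target, rose of 12 microRNA pathway genes (0 adjusted over the list alone; list adjusted p = 0.228). Neither the 4 epithelial markers (list adjusted p = 0.575) nor the 3 leukocyte markers (list adjusted p = 0.572) held a gene that passed over all genes. Adjusted over the list alone 1 epithelial and 1 leukocyte marker fell, KRT8 (-0.21) and CD68 (-0.19).

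In all, 482 genes rose and 1029 fell at 100 nM, with a median rise of 1.22-fold and a median fall of 1.20-fold; 46 rose and 24 fell by at least 1.5-fold. The 3 arrays at 100 nM and the 3 scrambled arrays did not overlap in 37.6% of genes, where chance gives 10%. Rises made up 31.9% of these calls but 44.6% with arrays centred on their medians (648 rose and 806 fell) and 44.1% with quantile normalization applied again (647 and 819), so the excess of falls moved with the scaling. Rises numbered 308 without scrambled replicate 3 and 293 without 100 nM replicate 2. Falls numbered 499 without scrambled replicate 2, 408 without scrambled replicate 3, 1559 without 50 nM replicate 2, 518 without 100 nM replicate 2 and 440 without 100 nM replicate 3. With array weights 1301 rose and 2433 fell, and with the axis covariate 794 and 1254.

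The calls at the 2 doses overlapped: 404 genes rose at both, 562 fell at both and 0 were called in opposite directions. Independent lists of these sizes would share 22.9 rises and 62.6 falls, a count that leaves out the scrambled arrays shared by both comparisons. In 100 simulations of unchanged groups against the same scrambled arrays 0 rises and 0 falls were shared. Unchanged groups seldom give calls, so this count could hardly differ from 0 and does not measure what the shared arrays add. Of 1661 genes called at either dose, 1654 (99.6%) had the same sign at both. Across genes, which are not independent replicates, the fold changes correlated at r = 0.928. In the same 100 simulations the mean r was 0.465, with a range of -0.655 to 0.982. Their covariance was 0.0249 against a simulated mean of 0.00319, a difference of 0.0217, and the highest simulated covariance was 0.0281. The 3 scrambled arrays cannot be split into parts of 2, so part of the overlap may come from the shared controls. Shared rises numbered 265 without scrambled replicate 3 and 266 without 100 nM replicate 2. Shared falls numbered 256 without scrambled replicate 2, 222 without scrambled replicate 3, 338 without 50 nM replicate 1, 327 without 100 nM replicate 2 and 335 without 100 nM replicate 3. They also numbered 366 in fits of only the 2 groups and 351 without the brightness minimum. With array weights 741 rises and 1378 falls were shared, and with the axis covariate 636 rises.

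**Figure D3:**
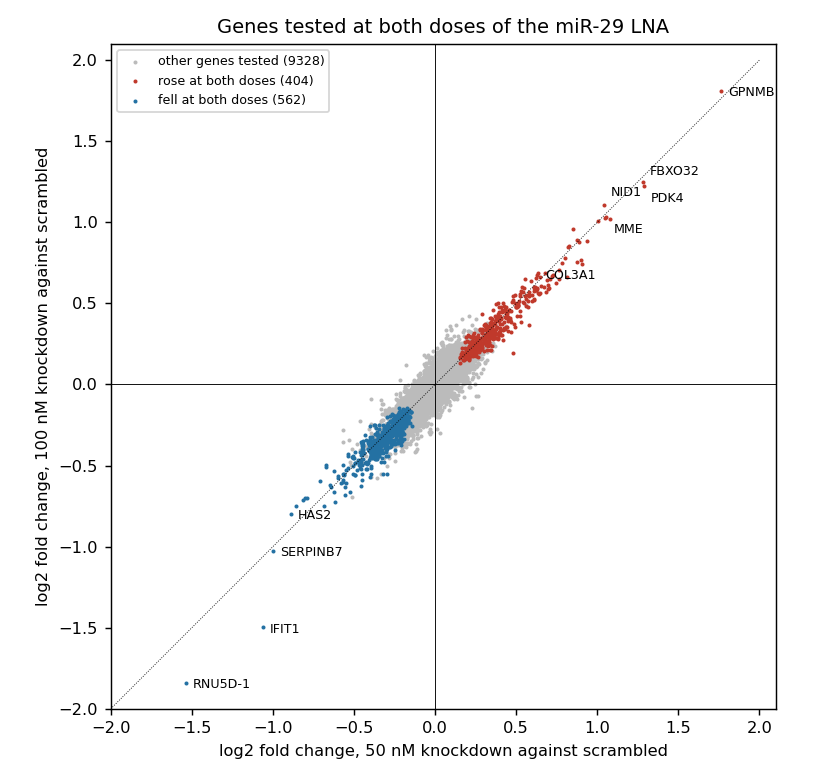
Log2 fold change against scrambled at 50 nM (horizontal axis) and 100 nM (vertical axis) for each of the 10294 genes tested, with the 404 genes that rose at both doses in red, the 562 that fell at both in blue and a dotted line of equal change. The called genes lie along that line, from RNU5D-1 at the lower left to GPNMB at the upper right.

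Between the doses no single gene passed. With limma 0 genes rose and 0 fell at 100 nM against 50 nM (lowest adjusted p 0.671), 300 genes had an unadjusted p under 0.05 where 515 are expected by chance, and array weights gave 1 rise and 3 falls. The largest differences, neither passing, were those of RNPC3 (0.30 ± 0.21, SE, adjusted p = 1) and IFIT1 (-0.43 ± 0.28, adjusted p = 1). The 95% interval of the difference lay within 1.5-fold either way for 99.9% of genes and within 2-fold for 100%, with a median half-width of 0.13 on the log2 scale. The groups did not overlap in 6.88% of genes, where chance gives 10%. Of the lists, fibrillar collagens lay higher at 100 nM as a set, with a mean difference of 0.04 and 0 of 9 members passing over all genes or over the list alone (adjusted p = 0.00588; adjusted p = 0.244 with an estimated correlation), and without 50 nM replicate 2 this call was lost (0.0684). Ribosomal protein genes lay lower as a set, with a mean difference of -0.08 and 0 of 22 members passing either way (adjusted p = 4.03e-06; adjusted p = 0.349 with an estimated correlation). Reported targets did not pass (adjusted p = 0.395): their median and mean differences were -0.002 and -0.005, while the test against other genes pointed up. Each of the other 20 lists also did not pass, with adjusted p from 0.0759 upward. Single arrays changed this for 5 of them. Integrins passed upward without 50 nM replicate 1 (0.0426), 50 nM replicate 3 (0.0312) or 100 nM replicate 3 (0.0467), and with quantile normalization applied again (0.0399). Interferon response genes passed downward without 50 nM replicate 3 (0.00738) or 100 nM replicate 2 (0.0369), contractile genes without 100 nM replicate 1 (0.0458), and cholesterol synthesis genes without 50 nM replicate 2 (0.012) or the 3 arrays highest on the axis (0.026). Leukocyte markers passed upward without 50 nM replicate 2 (0.0432). With dim members included p53 target genes (0.0228), interferon response genes (0.0339) and cholesterol synthesis genes (0.0318) passed downward and endothelial markers (0.00698) upward. With an estimated correlation none of these gained calls passed (adjusted p = 0.272 to 0.653).

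**Figure D4:**
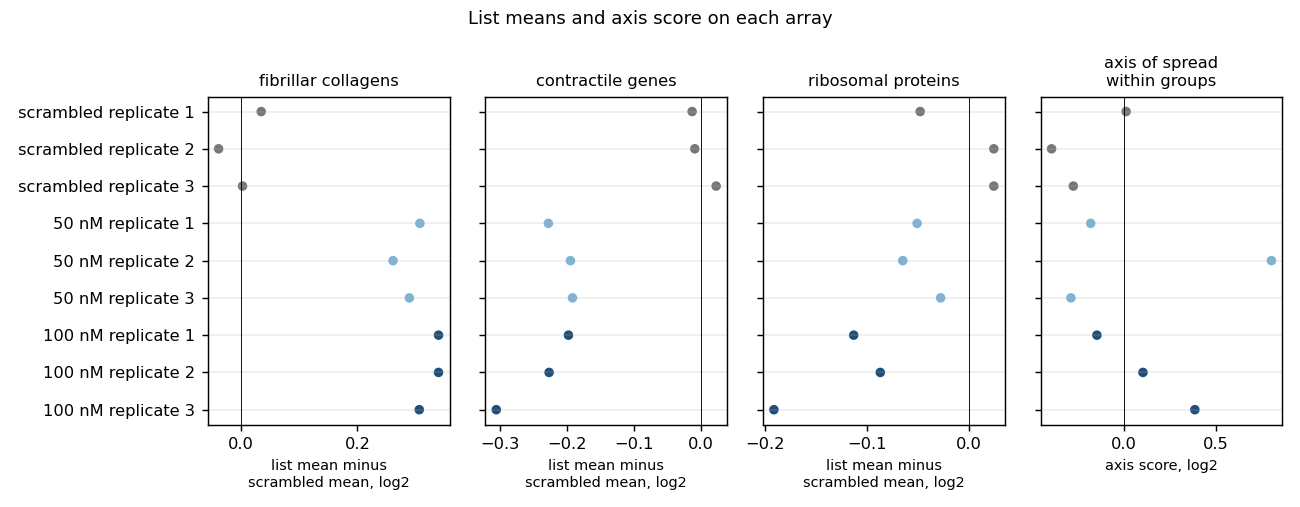
Mean over list members on each array minus the scrambled mean (log2, horizontal axis) for fibrillar collagens, contractile genes and ribosomal protein genes, and each array's score on the main axis of spread within groups (right panel). Fibrillar collagens lie at 0.26 or more on every knockdown array and contractile genes at -0.19 or less; ribosomal protein genes lie lowest on 100 nM replicate 3 (-0.19), and 50 nM replicate 2 has the highest axis score (0.80).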

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

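The tests without 100 nM replicate 3, without 50 nM replicate 2 and with the axis score as a covariate were chosen only after the results were seen. The fibrillar collagens and the ribosomal protein genes differed as sets between the knockdown doses, although no single gene did.

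Ribosomal protein genes, which encode the ribosome's structural proteins, lay lower at 100 nM than at 50 nM (camera adjusted p = 4.03e-06, mean log2 difference -0.08). The list mean relative to scrambled was -0.05, -0.07 and -0.03 on the arrays at 50 nM and -0.11, -0.09 and -0.19 on those at 100 nM. With the axis score as a covariate the mean log2 difference stayed at -0.082, but the mean score was 0.11 in both dose groups, so that fit could not move it and decides nothing. Without 100 nM replicate 3, the lowest array, it was -0.052 (SE 0.027), so that array may account for part of it and the design leaves its share open. An effect of the higher dose remains possible and was not tested further, and the call is lost with an estimated correlation (adjusted p = 0.349).

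Fibrillar collagens lay higher at 100 nM than at 50 nM (camera adjusted p = 0.00588, mean log2 difference 0.04). The list mean relative to scrambled was 0.31, 0.26 and 0.29 at 50 nM and 0.34, 0.34 and 0.31 at 100 nM. With the axis covariate the mean log2 difference stayed at 0.043, which for the same reason decides nothing. Without 50 nM replicate 2, the array with the highest axis score, it was 0.03 (SE 0.025). That does not decide between a dose effect and this array, since the difference less 50% of its first size does not exceed its standard error, and the call is lost with an estimated correlation (adjusted p = 0.244).

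Probe sets outside the genes tested, with no gene symbol or with several, also changed. Of 4538 such probe sets above the brightness minimum 11 changed at 50 nM (7 rose and 4 fell), 17 at 100 nM (8 rose and 9 fell) and 0 between the doses. At an unadjusted p under 0.05 (limma) these numbers were 577, 826 and 156. Among the 10294 genes tested the calls numbered 1116 at 50 nM and 1511 at 100 nM, a larger share. Probe set 8017843, which has no symbol here, rose by 1.28 at 50 nM and by 1.23 at 100 nM (adjusted p = 0.000242 and 0.000326). A probe set shared by MRPS6 and SLC5A3 rose by 0.52 and 0.53.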

How the results depend on the processing

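The fits with the axis score as a covariate, without the 3 arrays highest on the axis in their group, and on reported targets outside the matrix lists were chosen only after the data were seen. Of 1295 values of named genes under the alternatives, 1268 kept their side of the threshold, 21 no longer passed, 6 newly passed and 0 reversed. Of 1092 list tests these numbers were 1002, 54, 36 and 0. A reversal was counted only where a value passed with the deposited settings or with the alternative. Other changes of sign are among the values that kept their side. The list tests with other scalings are not among the 1092, and some lists newly passed with quantile normalization applied again. Between the doses every alternative except array weights gave 0 genes. With array weights 1028 genes rose and 1568 fell at 50 nM, 1301 and 2433 at 100 nM, 741 and 1378 at both, and 1 and 3 between the doses. With at least 1.5-fold required 54 rose and 19 fell at 50 nM, 46 and 24 at 100 nM, and 43 and 14 at both, since the threshold removes small changes. Without the brightness minimum 393 fell at 50 nM and 351 at both, and in fits of only the 2 groups compared 376 and 366. With the axis covariate 784 rose at 50 nM, 794 at 100 nM and 636 at both. The axis was taken from the spread within groups on these same arrays, so fitting it lowers that spread and favours more calls. Calls gained this way are therefore not independent support. The causes of the other moves were not tested.

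With the preset correlation 9 lists moved up and 1 down at 50 nM, 11 and 2 at 100 nM, and 1 and 1 between the doses. With an estimated correlation all 6 counts were 0. In other settings, tested so after the data were seen, 6 of 69 list tests passed with it without the brightness minimum, and 2 each with the axis covariate and with quantile normalization applied again. The reported targets passed in all 3 (adjusted p = 0.000966 to 0.0476), and without the brightness minimum basement membrane and cell cycle genes did too (0.0256). With each single array left out 0 passed camera so (7 to 9 before adjustment). Fry, which tests a list against no change and not against other genes, gave 4 down at 100 nM, and 0 up and 0 down between the doses. Without the brightness minimum 3 moved down at 50 nM, 7 up and 4 down at 100 nM, and 2 up and 4 down between the doses, with more members tested. Without the 3 arrays highest on the axis 7 moved up at 100 nM and 2 down between the doses.

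Leaving out each array in turn gave 335 to 557 rises and 259 to 602 falls at 50 nM, 293 to 688 and 408 to 1559 at 100 nM, 265 to 465 and 222 to 516 at both, and 0 to 0 between the doses. Lists up numbered 8 to 10 at 50 nM, 8 to 12 at 100 nM and 1 to 2 between the doses, and lists down 1 to 1, 2 to 2 and 1 to 2. The lowest counts of rises at 50 nM and of falls at both doses came without scrambled replicate 3.

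With a replicate block 340 genes rose and 340 fell at 50 nM, 329 and 566 at 100 nM, and 279 and 291 at both. MCL1 (adjusted p = 0.066 and 0.0583) and the proteases at 50 nM (0.0501) then missed the threshold. Deviations correlated best with an array of the same number in 1 of 9 arrays, so the numbers gave no pairing. No seed site test was run, since no sequences were used here. Genes below the brightness minimum, such as DNMT3B and TET1, limit what the signal shows.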

Other observations

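The lists in this part, except the interferon list fixed earlier, were chosen only after the largest changes were seen, and were tested without the genes that prompted them. Also chosen then were the tests of FoxO, ATF4 and interferon genes, some of whose members' values were known, and the test with the axis covariate. The interferon test largely repeats the one with dim members given in the Results, now without IFIT1. The 5 lists gave 10 tests at both doses, adjusted together for the values below. Genes named here fall outside the naming rule and were chosen after their values were seen.

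PHGDH and PSAT1, enzymes of serine synthesis, and ASNS, which makes asparagine, rose at both doses, while PSPH, a further enzyme of serine synthesis, did not pass (log2 -0.09 and -0.01). PHGDH rose 1.53-fold at 50 nM and 1.52-fold at 100 nM, PSAT1 1.78-fold and 1.81-fold, and ASNS 1.47-fold and 1.57-fold. A hypothesis is that targets of ATF4, a transcription factor of amino acid stress, rose more widely. Of 18 other targets tested 7 rose and 2 fell at 50 nM and 6 rose and 2 fell at 100 nM (camera gave 0.000108 and 6.63e-05 before adjustment, adjusted p = 0.00018 and 0.000133). The amino acid transporter gene SLC7A5 rose by 0.48 and 0.52, while PYCR1 and ALDH18A1 of proline synthesis fell by 0.20 and 0.25 at 50 nM. The shift is consistent with the hypothesis only at camera's preset correlation: with an estimated correlation it did not pass (adjusted p = 0.15 at both doses). Of the 18 genes 3 are also in a list fixed earlier.

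Lysosomal genes form another such group. GPNMB and the lysosomal protease gene CTSK (1.70-fold and 1.57-fold) prompted the hypothesis that lysosomal genes rose widely. Of 20 others tested 11 rose at 50 nM and 9 at 100 nM, and 0 fell (camera gave 6.74e-10 and 1.59e-07 before adjustment, adjusted p = 6.74e-09 and 7.95e-07). NPC2, which carries cholesterol out of lysosomes, rose by 0.42 and 0.27, and the protease CTSD by 0.34 and 0.21. This is consistent with a broad rise of lysosomal genes at the preset correlation, but with an estimated correlation it did not pass (adjusted p = 0.15 and 0.171).

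A wider rise of NRF2 targets, genes of the oxidative stress response, was tested because AKR1C1 (1.91-fold and 1.85-fold) and AKR1C3 (1.87-fold and 1.70-fold) rose. Of 15 others 3 rose at 50 nM and 4 at 100 nM, and 0 fell (camera gave 0.00258 and 0.015 before adjustment, adjusted p = 0.00369 and 0.0188). HMOX1 rose by 0.33 and 0.26, while NQO1 did not pass (0.03 and -0.01). With an estimated correlation the list did not pass (adjusted p = 0.31 and 0.385), so a wider rise may not hold. For FoxO targets, asked because PDK4, FBXO32 and KLHL24 (1.74-fold and 1.72-fold) rose, 0 of 16 others changed at 50 nM and 2 rose and 2 fell at 100 nM (camera gave 0.612 and 0.541 before adjustment). Members went both ways, and the test does not decide.

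A wider fall of interferon response genes beside IFIT1 was tested with dim members included. Of 25 members 0 changed at 50 nM and 4 fell at 100 nM, MX1, IFIH1, RIGI and DDX60, with medians of -0.22 and -0.36 (camera gave 5.44e-05 and 8.51e-06 before adjustment, adjusted p = 0.000133 and 2.84e-05). The list thus lay lower at the preset correlation, but with an estimated correlation it did not pass (adjusted p = 0.187 and 0.171). No untransfected group was measured, so a fall with the miR-29 LNA cannot be told from a rise with the scrambled one.

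Of the reported targets, 21 of 39 tested are outside the matrix and integrin lists. Of these 9 rose and 0 fell at each dose, with medians of 0.17 and 0.18 (camera adjusted p = 1.65e-08 at both over 3 comparisons; adjusted p = 0.0131 at both with an estimated correlation). All 39 together did not pass with an estimated correlation when adjusted over 69 list tests (adjusted p = 0.0885), and these 21 were not tested in that larger family.

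The genes changed at both doses were weighed against the axis of spread, whose mean score was higher at 100 nM than in scrambled and, through replicate 2 alone, at 50 nM, and whose loadings correlated with the fold changes across genes (r = 0.355 and 0.346). Of the 562 genes that fell at both doses 82.2% loaded negatively on it, and so did 72.8% of the 404 that rose at both. The median loading was -0.091 for the genes that fell and -0.057 for those that rose, against -0.039 for all protein-coding genes tested. With the axis score as a covariate the median fall shrank from -0.288 to -0.252 at 50 nM and from -0.309 to -0.278 at 100 nM. The median rise grew from 0.335 to 0.35 and from 0.311 to 0.332. With the axis score as a covariate 100% of the genes that fell and 100% of those that rose kept at least 50% of their log2 change at both doses. Passing the threshold takes a change that is large for the spread within groups, which favours genes loading weakly on this axis for the size of their change. That outcome was thus favoured in advance and is not held against the axis. The contractile genes were fixed as a list before the data were examined. With the covariate their median was -0.14 at 50 nM and -0.22 at 100 nM (-0.15 and -0.21 without it, SE of the list mean 0.03). The list was weighed here because it had passed, which also favours little spread within groups, so these medians alone do not decide. The axis scores of 50 nM replicates 1 and 3 and 100 nM replicate 1 lay within the scrambled range. Their contractile list means were still -0.23, -0.19 and -0.20 relative to scrambled, where single scrambled arrays lay between -0.01 and 0.02. These values argue against the axis as the whole cause of the contractile fall. An effect of the miR-29 LNA remains a hypothesis, as do sequence effects of the oligonucleotide beyond miR-29, which no group tests. The 10 ways of splitting the 6 arrays are too few for a share under 0.05: the real split called 1116 genes at 50 nM and 1511 at 100 nM, and the highest of the other 9 was 0 in both, so 1 of 10, the real split itself, reached that count. Between the doses all 10 splits, the real one included, gave 0.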
